A study of Rattus norvegicus with 65 samples.

How the data were processed

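Gene expression was measured in rat mammary tumors on 65 Affymetrix arrays. Per the labels, frozen tumor tissue gave total RNA through a spin-column kit, and 6 µg of it was turned into biotin-labelled cRNA for each array. The deposited values are probe set intensities on a linear scale, from 1 to 12011, with the lowest value exactly 1 on all 65 arrays. How the authors summarised the probes and normalized the arrays is not given in the sources used here. No detection call was used.

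Each array was assigned to a transplant series and a generation from its title. The 11 series were numbered 10, 13, 17, 19, 25L, 25R, 32, 33, 34, 36 and 42, and the 6 generations were the primary tumor and transplants 1 to 5. Series 25L and 25R share a number, and the labels do not say whether they came from 1 animal. They were treated as separate lines, although their arrays correlated with each other at a mean of 0.21, against 0.19 within 25L, 0.25 within 25R and -0.04 between series. The transplant 5 tumor of series 10 was not analysed here. No 2 arrays held identical values.

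The median intensity per array, before scaling, ranged from 96.1 to 176. Each array was scaled to the common median of 162 over 15866 probe sets that were not controls (57 control probe sets were left out). Values under the pooled 10th percentile, an intensity of 39.8, were set to it, and log2 was taken, so the floor lies at 5.31. Values at the floor carry no order, and a change against a group at the floor is a lower bound. Probe sets with a mean log2 below 6.35, the lowest 25%, were left out of the tests. Of the 15866 probe sets, 12783 had 1 gene symbol, 312 had several and 2771 had none in the platform annotation, and 12754 gene identifiers matched the current rat annotation (assembly GRCr8), which was used for names. Each of 10411 genes was read from its brightest probe set, and 8499 genes were tested. Array precision is limited by the number of arrays, and the deposited values carry no counts or depth.

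Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on log2 values, Benjamini-Hochberg adjustment over the 8499 genes and a two-sided threshold of 0.05. All arrays entered 1 fit with generation and series as factors, so that each tumor was compared within its own line of descent. The pairing comes from the design text, which describes lines transplanted from a first tumor. Arrays of 1 series deviated together: for 50 of 65 arrays (76.9%) the most correlated other array belonged to the same series, against a highest value of 20 in 10000 permutations (permutation p = 1e-04, the smallest they can give). The mean correlation was 0.38 within series and -0.04 between series, and in 3 of 11 series every pair of arrays exceeded 0.1. The fit treats the arrays of a line as independent once the line's mean is removed, although each tumor descends from the one before it. A fit with 1 value per series, which does not assume this, was added after seeing the data.

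The comparisons were the mean of the transplants minus the primary tumor, transplant 5 minus primary, transplant 1 minus primary, the linear slope per transplant over transplants 1 to 5, any difference among generations, differences among series, and differences among series in slope (over the 54 transplant arrays). Gene lists were tested with camera (preset correlation 0.01), with camera under an estimated correlation, with fry, and with an exact sign-flip permutation test of the list mean per series. Differences in the slope of a list among series were tested with 100000 permutations. The comparisons above, their tests, 33 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Exceptions were the list tests for transplant 1 and the permutations of list slopes among series, which that plan did not hold. It also held no comparison of the other single transplants with the primary tumor or of adjacent generations. The lists were mitosis, DNA replication, luminal epithelium, hormone response, milk secretion, basal myoepithelium, mesenchymal genes, epithelial junctions, matrix proteases, fibroblast matrix, basement membrane, endothelium, adipocytes, skeletal muscle, macrophages, T and NK cells, B and plasma cells, mast cells, granulocytes, red blood cells, interferon response, antigen presentation, hypoxia and glycolysis, growth factor signalling, the Wnt pathway, the proteasome, endoplasmic reticulum stress, immediate early genes, cholesterol synthesis, lipogenesis, oxidative phosphorylation, ribosomal proteins and 1 list unnamed here. They held 556 tested genes, and the junction and luminal lists share 4 genes.

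Named genes were the 10 with the largest rise and the 10 with the largest fall past the threshold that went the same way in at least 9 of 11 series, for the transplants against primary and for the slope. For transplant 5, 5 each way were taken that agreed in at least 8 series with both arrays. The 10 genes with the largest share of variance between series, the 5 with the most different slopes, up to 4 called genes per list (otherwise up to 2 of its brightest) and 11 genes set in advance (Esr1, Pgr, Erbb2, Cdh1, Vim, Krt8, Krt14, Mki67, Hras, Mmp9 and 1 unnamed here) were also taken. Probe sets of Mvk, Myh1 and Sfrp4 other than the one used had the opposite sign.

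The tests were tried on simulated data. Over 8499 genes, 85% of genes shifted by 0.5 and 96% of those shifted by 1 on the log2 scale were recovered for the transplants against primary (6 false among 187 calls). For the slope, 77% and 93% were recovered (4 false among 174 calls). Without a change, 0 genes were called in each of 6 comparisons, and differences among series were not simulated. Camera called 5 of 5 lists shifted by 0.4 and 0 of 5 unshifted lists. The simulated noise was independent between arrays and between genes, whereas consecutive tumors of a line were correlated (mean 0.29 to 0.72). The simulation therefore cannot show how many false calls the real arrays give.

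The alternatives were no series block, series as a random block, series 25L and 25R joined, quantile normalization, centring on the median, no filter, a filter at the median, all probe sets, eBayes with trend and robust settings, array weights, the log2 ratio of the 3' to the 5' Gapdh control probe sets as a covariate, log2 of the value plus 16 without a floor, and leaving out each series. Added after seeing the data were the fit with 1 value per series, leaving out the transplant 5 array of series 32, arrays that were not rescaled and sign-flip tests with series 25L and 25R averaged to 1 value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.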

Results

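Carcinogen-induced rat mammary tumors were passed through 5 generations of syngeneic hosts, and each generation was profiled on an Affymetrix array. There were 11 primary tumors, 11 tumors each of transplants 1 to 4 and 10 of transplant 5. The design text says that the tumors vary in invasive and metastatic behaviour, but the labels give no phenotype per tumor, so expression was compared by generation and by line. Each line is 1 series, and generations were compared within lines.

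Tumors differed more between lines than between generations. Cd9, a tetraspanin of epithelial membranes, had the largest share of its variance between lines (96.0%). In series 42 it averaged 5.66 ± 0.41 (SD, n = 6 arrays) on the log2 scale, against means of 10.42 to 11.21 in the other 10 series. Met, the receptor for hepatocyte growth factor, was at 11.67 ± 0.22 (SD, n = 6 arrays) in series 42 and at means of 6.06 to 7.37 elsewhere (90.5% of variance). Ankib1 (93.7%), Cnot10 (92.6%), Rab14 (91.6%), Sh3d19 (91.2%), Scaf1 (90.7%), Purb (90.7%), Gatad1 (90.5%) and Fitm1 (89.9%) completed the 10 genes with the largest shares. Ankib1, Purb and Gatad1 also set series 42 apart, with means of 10.06, 10.17 and 11.11 there. Scaf1 was near the floor in series 10, 17, 19, 25L and 25R (means 5.31 to 5.49) and at 6.75 to 7.94 in the others. Rab14 split the same series, at means of 11.20 to 11.48 against 9.62 to 10.36. What these groups of series share was not tested. The 6 arrays of series 42 also had median intensities of 143 to 147 before scaling, and a difference in array processing between lines was not tested. By limma, 7099 of 8499 genes (83.5%) differed among series and 407 (4.79%) among the 6 generations at an adjusted p below 0.05. The median share of a gene's variance was 42.9% for series (interquartile range 31.6 to 55.4), 6.06% for generation and 49.3% for the remainder, where degrees of freedom alone would give 15.6%, 7.81% and 76.6%. These chance shares hold only if neither series nor generation has an effect, so 6.06% against 7.81% does not place generation below chance. The count among generations fell to 8 without the series block, and to 260, 195, 271, 242, 196 and 221 without series 13, 17, 19, 25R, 32 and 34.

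Relative to the primary tumors, Cxcl14, a chemokine of epithelia, fell by 2.00 ± 0.33 (SE) on the log2 scale in the transplanted tumors and was lower in 10 of 11 series (limma adjusted p = 0.000101). Penk, the enkephalin precursor, fell by 2.18 ± 0.39 (10 of 11 series), and Sfrp2, a secreted Wnt modulator, fell by 1.98 ± 0.37 (9 of 11). Mmp7, a matrix metalloproteinase, fell by 1.78 ± 0.29, the tight junction gene Cldn3 by 1.75 ± 0.31 and the prolactin receptor gene Prlr by 1.57 ± 0.34, each lower in 10 series. Mup5 (-2.68), Clca1 (-1.94), the lipid transporter gene Mfsd2a (-1.66) and Reln (-1.49, lower in 11 of 11) also fell. The Mup5 probe set belongs to a type that can detect related genes, so its identity is uncertain.

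Among the genes that rose, Sostdc1, a secreted antagonist of BMP and Wnt signals, was higher by 1.72 ± 0.29 (SE; 3.30-fold) and higher in 10 series, with 5 primary tumors at the floor. Ocm, a calcium-binding protein gene, was at the floor in all 11 primary tumors, so its rise was at least 2.53-fold. Vim, the intermediate filament of mesenchymal cells, rose by 0.97 ± 0.17 (10 of 11 series, limma adjusted p = 0.000185), and Gnai1, an inhibitory G protein subunit, by 0.91 ± 0.16 (11 of 11). S100a4, a calcium-binding protein of motile cells, rose by 1.27 ± 0.40 (limma adjusted p = 0.0324). Gpr15lg (1.22), S100a9 (1.19), Cdhr1 (1.17), Lrg1 (1.05) and Emp3 (0.93) rose in 9 or 10 series. Over all genes, limma called 807 of 8499, 377 up and 430 down, of which 8 rose and 30 fell at least 2-fold. With 1 value per series the count was 135 (45 up, 90 down), and 12 of the 20 genes named here stayed past the threshold, the exceptions being S100a4, Gpr15lg, S100a9, Lrg1, Vim, Emp3, Penk and Clca1. Without the series block the count was 85, with array weights 331, with the Gapdh 3' to 5' ratio as a covariate 407, and without series 17 or 25R it was 488 or 495. Calls were lost for S100a4 without series 17, 25R, 32 or 34 (adjusted p = 0.0918, 0.0914, 0.154 and 0.0730), for Emp3 without 17, 25R, 32 or 36 (0.0732, 0.0740, 0.129 and 0.0580) and for Lrg1 without 25R or 33 (0.0561 and 0.0526). S100a9 lost its call without any 1 of 10, 13, 17, 25L, 25R, 32, 33 or 34 (0.0571 to 0.140). Of the 20 named genes 16 stayed called with the Gapdh covariate, which ended the calls of S100a4, S100a9, Lrg1 and Emp3. Array weights kept 16 and ended those of S100a9, Lrg1, Emp3 and Clca1. Without the series block 6 stayed called (Mup5, Penk, Cxcl14, Sfrp2, Mmp7 and Mfsd2a). Without rescaling of the arrays 28.7% of the calls were up, against 46.7% with it.

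Members of several gene lists were called, while no list was called with an estimated correlation (adjusted p = 0.246 to 0.998). In the mitosis list 5 of 20 genes rose and none fell (14 adjusted over the list alone), including Ccnb1 (0.65 ± 0.17), Racgap1 (0.63 ± 0.21), Cks2 (0.63 ± 0.19) and Mki67 (0.58 ± 0.19). The DNA replication list had 4 of 23 genes up (7 adjusted over the list alone), among them Mcm6 (0.52 ± 0.16) and Rrm1 (0.48 ± 0.13), and its mean was higher in 10 of 11 series. Of 31 hypoxia and glycolysis genes 10 rose (13 adjusted over the list alone), led by Ndrg1 (0.81 ± 0.24), P4ha1 (0.62 ± 0.16) and Tpi1 (0.55 ± 0.13). Antigen presentation had 2 of 18 genes up (5 adjusted over the list alone), RT1-N3 (0.46 ± 0.10) and RT1-DMb (0.37 ± 0.12), and its mean was higher in 10 of 11 series. Of 18 mesenchymal genes 3 rose (4 adjusted over the list alone), and of 16 cholesterol synthesis genes 2 rose (2 adjusted over the list alone), with Insig1 at 0.64 ± 0.16. For both lists the adjusted p was 0.545 with an estimated correlation. In the proteasome list 3 of 23 genes rose (5 adjusted over the list alone).

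In the luminal epithelium list 5 of 18 genes fell and none rose (6 adjusted over the list alone). The list mean was -0.60, with adjusted p = 0.545 with an estimated correlation. Prom1 (-1.22 ± 0.18) was lower in 11 of 11 series, and Tspan8 (-1.11 ± 0.29) and the mucin gene Muc1 (-0.68 ± 0.22) fell as well. Of 18 epithelial junction genes, Cldn3 alone was called (1 adjusted over the list alone), with a list mean of -0.47. Of 14 hormone response genes 4 fell and 1 rose (5 and 2 adjusted over the list alone). The fallers included the growth factor gene Areg (-1.85 ± 0.42), Irs2 (-0.97 ± 0.19) and Igf1r (-0.58 ± 0.15). In the fibroblast matrix list Bgn rose (1.22 ± 0.28) and Sfrp2 fell (1 and 1 adjusted over the list alone), and no macrophage gene was called (0 adjusted over the list alone).

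By camera, 13 of 32 lists were called, these and 1 unnamed here, from adjusted p = 9.2e-07 for mitosis and 2.9e-06 for luminal epithelium to 0.043 for fibroblast matrix. None was called with an estimated correlation, where the adjusted p was 0.246 for hormone response, 0.756 for macrophages, 0.777 for the proteasome, 0.870 for fibroblast matrix and 0.545 for each of the other 9. Fry called 6 of the 32 lists and the exact sign-flip test 2 (DNA replication and antigen presentation, adjusted p = 0.0469 each), with an adjusted sign-flip p of 0.0714 for mitosis and luminal epithelium and 0.342 for mesenchymal genes. With series 25L and 25R averaged to 1 value, the exact sign-flip test called 0 lists in each of the 4 comparisons, with an adjusted p of 0.0938 for DNA replication and antigen presentation. With the 10 values left, or 9 at transplant 5, 1 list alone at the smallest p the test can give would not pass over 32 lists. The loss of these calls is therefore weak evidence against the lists. The mesenchymal call was lost without series 32 (adjusted p = 0.0793). Calls were also lost without series 10 or 13 for hormone response (adjusted p = 0.0523 and 0.0605) and 17, 32 or 33 for macrophages (0.0563, 0.112 and 0.0536). The proteasome call was lost without any 1 of 13, 19, 25L, 32 or 33 (0.0503 to 0.121), and the fibroblast matrix call without any 1 of 17, 19, 25R, 32, 33, 34 or 36 (0.0743 to 0.830) and without the transplant 5 array of series 32 (0.0603). Other settings ended calls too. The proteasome call was lost without the series block (0.0583), with quantile normalization (0.184), a filter at the median (0.0507), the Gapdh covariate (0.0673) and no rescaling (0.0673). Fibroblast matrix was lost with quantile normalization (0.0589), a filter at the median (0.0853) and the Gapdh covariate (0.197), macrophages with the Gapdh covariate (0.0661), and hormone response with array weights (0.0922) and a filter at the median (0.0853).

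The other lists were not called by camera. Their mean log2 differences were 0.20 for adipocytes, 0.18 for granulocytes, 0.11 for T and NK cells, 0.10 each for endothelium, interferon response and the Wnt pathway, 0.06 each for oxidative phosphorylation, endoplasmic reticulum stress and lipogenesis, 0.05 for immediate early genes, 0.04 for skeletal muscle and 0.03 for ribosomal proteins. They were -0.04 for basement membrane and red blood cells, -0.05 for mast cells, -0.06 for matrix proteases, -0.10 for growth factor signalling and -0.14 each for basal myoepithelium and milk secretion. The B and plasma cell list had 1 tested gene, Cxcr5, at 0.05 and was not tested as a list. The ribosomal mean turned to -0.016 with quantile normalization and to -0.0037 without rescaling. The camera direction opposed the list mean for the Wnt pathway, skeletal muscle, red blood cells and immediate early genes, and the median opposed it for milk secretion and matrix proteases. For transplant 5 the mean, median and camera direction did not all share a sign for growth factor signalling, immediate early genes, lipogenesis, red blood cells and the Wnt pathway. For the slope this held for adipocytes, antigen presentation, basement membrane, granulocytes, growth factor signalling and the Wnt pathway. Single members of these lists were called: the receptor genes Fgfr3 (-0.89 ± 0.19), Met (-0.52 ± 0.16) and Egfr (-0.51 ± 0.16) fell while Hbegf (0.50 ± 0.15) rose, Xbp1 (-0.46 ± 0.11) fell and Sel1l (0.40 ± 0.10) rose.

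**Figure D1:**
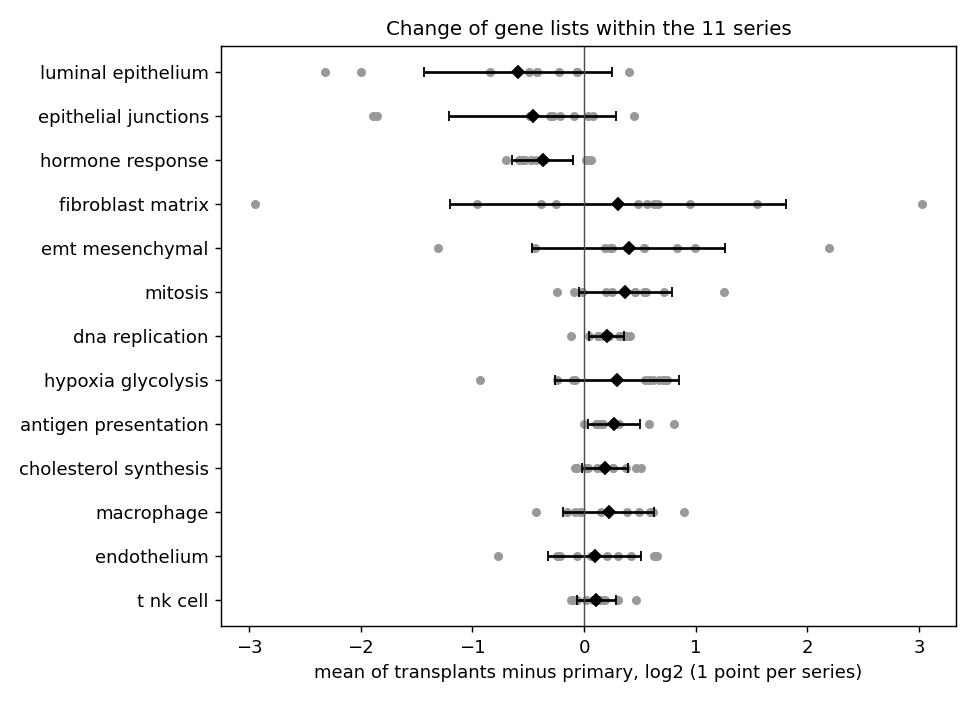
Mean log2 difference of 13 gene lists between the transplants and the primary tumor of the same series (horizontal axis). Gray points are the 11 series and black diamonds with bars are the mean and SD. The DNA replication and antigen presentation means were above 0 in 10 of 11 series, and the luminal epithelium mean was below 0 in 10 of 11.

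The first passage alone gave no called gene. By limma 0 of 8499 genes passed for transplant 1 against primary, with 584 at an unadjusted p below 0.05, and the smallest adjusted p was 0.0982. Camera called 9 lists upward in this comparison, among them hypoxia and glycolysis (mean 0.26), antigen presentation (0.27) and mitosis (0.24), with adjusted p = 0.792 for each of these 3 with an estimated correlation. Fry called 0 lists and the exact sign-flip test 0 (lowest adjusted p 0.603). The count against primary grew with each generation, to 143, 258, 534 and 1197 genes at transplants 2, 3, 4 and 5. These counts come from the fit of all arrays, which treats the arrays of a line as independent once the line's mean is removed. With 1 value per series the count at transplant 5 was far lower, as given below. Swapping the primary and transplant 5 labels in random subsets of series gave up to 1241 genes. Between adjacent generations limma called 0 genes at every step, with 584, 195, 202, 88 and 331 genes at an unadjusted p below 0.05.

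**Figure D2:**
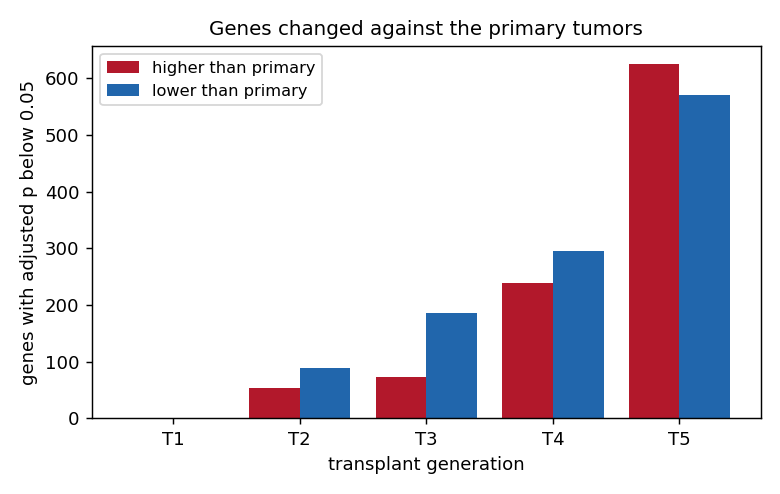
Number of genes with a limma adjusted p below 0.05 against the primary tumors (vertical axis) in each transplant generation (horizontal axis), as bars for higher and lower genes. The bars rise from 0 at transplant 1 to 626 higher and 571 lower genes at transplant 5. The counts are from the fit of all arrays, which treats the arrays of a line as independent once the line's mean is removed.

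At transplant 5 S100a4 rose by 2.41 ± 0.52 (SE; 5.33-fold, 10 of 10 series, limma adjusted p = 0.00195), Emp3 by 1.93 ± 0.38, the galectin gene Lgals1 by 1.74 ± 0.49, S100a9 by 1.73 ± 0.52 and the matrix protein gene Tgfbi by 1.63 ± 0.34. Csn3, which encodes kappa-casein, fell by 2.49 ± 0.54 (10 of 10 series, limma adjusted p = 0.00186), and Lalba, which encodes alpha-lactalbumin, fell by 2.39 ± 0.69. Olah, a thioesterase gene of milk fat synthesis, fell by 2.57 ± 0.63, Clca1 by 2.53 ± 0.67 and Mup5 changed by -3.36 ± 0.59. In the luminal list 9 of 18 genes fell (11 adjusted over the list alone), including Krt19 (-1.64 ± 0.58) and Epcam (-1.56 ± 0.50), and its mean was lower in 10 of 10 series. The size was uneven: at transplant 5 Epcam was at 5.58 in series 32, 5.31 in series 34 and 9.46 in series 36. It was at 10.87 to 11.59 in series 13, 17, 19, 25L, 25R and 33, and at the floor in series 42 at transplants 1 and 5. Of 18 junction genes 8 fell (13 adjusted over the list alone), with Cldn7 at -1.36 ± 0.39 and St14 at -1.01 ± 0.29. Of 13 milk secretion genes 4 fell (4 adjusted over the list alone), and of 18 mesenchymal genes 5 rose (6 adjusted over the list alone), with the fibronectin gene Fn1 at 1.5 ± 0.47. Mitosis had 7 of 20 genes up (16 adjusted over the list alone) and hypoxia and glycolysis 10 of 31 (19 adjusted over the list alone). For these 6 lists the adjusted p was 0.53 with an estimated correlation. Lists of other cell types were also called upward by camera: fibroblast matrix with a mean of 0.54 (2 of 27 genes up and 1 down, the same adjusted over the list alone), macrophages with 0.35 (2 of 17 up and 1 down, 3 and 1 adjusted over the list alone) and T and NK cells with 0.25 (1 of 14 up, 0 adjusted over the list alone). Their adjusted p with an estimated correlation was 0.708, 0.608 and 0.608. The fibroblast call was lost without series 25R, 32 or 36 (adjusted p = 0.136, 0.336 and 0.0639) or the transplant 5 array of series 32 (0.0514). The macrophage call was lost without series 32 (0.111), and the T and NK cell call without series 32 (0.420) or that array (0.380) and with a filter at the median (0.165). Erbb2, a growth factor receptor gene, fell by 0.60 (limma adjusted p = 0.0355).

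In all, limma called 1197 of 8499 genes at transplant 5, 626 up and 571 down, with 57 up and 88 down at least 2-fold. With 1 value per series the count was 133 (56 up, 77 down), and 6 of the 10 genes named by size stayed past the threshold (S100a4, Emp3, Tgfbi, Mup5, Olah and Csn3). It was 37 without the series block, 307 with array weights, and 764 and 778 without series 17 and 34. Calls were lost for Lgals1 without series 32 or 34 (adjusted p = 0.0648 and 0.0506), for Lalba without 36 (0.0513) and for S100a9 without any 1 of 13, 17, 25R, 32, 33 or 34 (0.0504 to 0.0624). Of these 10 genes, array weights kept 6 (S100a4, Emp3, Lgals1, Tgfbi, Mup5 and Csn3), and Mup5 alone stayed called without the series block. Without rescaling, 16.8% of calls were up instead of 52.3%, and the median of all genes moved by -0.11. Camera called 17 lists (11 up, 6 down) and none with an estimated correlation, where the smallest adjusted p was 0.442. Fry called 8 lists and the exact sign-flip test 0 (lowest adjusted p 0.0625). The luminal list, lower in 10 of 10 series, had the smallest p that the sign-flip test can give. Over 32 lists, 1 list alone at that p would not pass, so the 0 sign-flip calls decide little. Of the 17 lists, 10 stayed called without the transplant 5 array of series 32 and 12 each with quantile normalization, with a filter at the median and without rescaling, where the milk secretion call was lost (adjusted p = 0.0591).

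**Figure D3:**
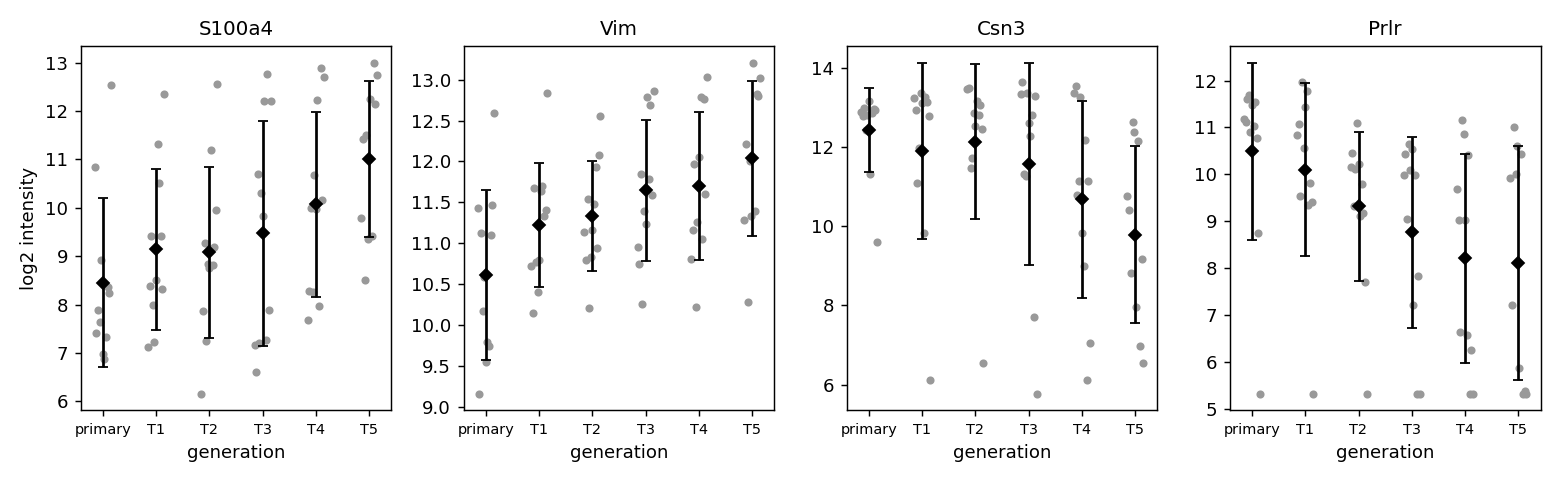
Log2 intensity (vertical axes) of S100a4, Vim, Csn3 and Prlr by generation (horizontal axes). Gray points are tumors and black diamonds with bars are the mean and SD. S100a4 averaged 8.45 in primary tumors and 11.01 at transplant 5, and Csn3 averaged 12.43 and 9.78.

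Across transplants 1 to 5, 20 genes were named by slope among the called genes that went the same way in at least 9 of 11 series. For Clmp and Epcam 1 of the 9 series had at most 1 transplant above the floor, where values carry no order, which leaves 8. Per transplant, S100a4 rose by 0.45 ± 0.12 (SE), Emp3 by 0.41 ± 0.08, Lgals1 and Tgfbi by 0.38 each, Pcolce by 0.34, Fads3 by 0.32, Cd44, the hyaluronan receptor, by 0.31 ± 0.05 (limma adjusted p = 0.000739), Col5a1 and Clmp by 0.31 each and Angptl2 by 0.29. The falling genes were Gp2 (-0.57), Igfbp2 (-0.55), Csn3 (-0.54 ± 0.12), Csn1s1 (-0.51), Prlr (-0.49), Mylk (-0.41, with a slope below 0 in 11 of 11 series), Epcam (-0.40 ± 0.11), Tc2n (-0.35), Prss8 (-0.35) and Rph3al (-0.34). In the luminal list 9 of 18 genes fell (13 adjusted over the list alone), among them Krt19 (-0.49 ± 0.13) and Krt18 (-0.43 ± 0.12). Of 18 junction genes 8 fell (11 adjusted over the list alone), including Cdh1, which encodes E-cadherin (-0.35, limma adjusted p = 0.0413), and of 17 basal myoepithelium genes 6 fell (9 adjusted over the list alone), including Krt5 (-0.39 ± 0.12). Of 18 mesenchymal genes 4 rose (7 adjusted over the list alone), and macrophage genes had 1 up and 1 down (12 up and 1 down adjusted over the list alone), with Lyz2 at 0.20 ± 0.06 and Cd14 at -0.20 ± 0.06. Camera called 14 lists, fry 6 and the exact sign-flip test 0 (lowest adjusted p 0.0625). The adjusted p with an estimated correlation was 0.257 for the luminal, junction and basal lists, 0.304 for the mesenchymal and 0.630 for the macrophage list. Fibroblast matrix (mean slope 0.16), T and NK cells (0.05) and endothelium (0.05) were called upward as well, with adjusted p = 0.630, 0.630 and 0.660 with an estimated correlation. The T and NK cell call was lost without series 13 or 32 (0.1002 and 0.131) or the transplant 5 array of series 32 (0.176), and the endothelium call without series 13, 25L, 25R or 32 (0.196, 0.0832, 0.0519 and 0.104) or that array (0.0783).

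Limma called 410 genes with a slope, 173 up and 237 down. The count rested on few lines: it was 7, 4 and 3 without series 32, 34 and 36, 261, 812 and 686 without series 13, 25L and 33, and 72 without the transplant 5 array of series 32. Without series 34 or 36, Cd44 was the only gene of the 20 named above that stayed past the threshold (adjusted p of the others 0.0731 to 0.196). Without series 32 Emp3 and Tgfbi stayed too (others 0.0644 to 0.186), and without its transplant 5 array 10 of the 20 stayed (others 0.0503 to 0.0977). Lgals1 also lost its call without series 17 or 25L, and Col5a1, Clmp and Angptl2 without any 1 of several further series, with an adjusted p of at most 0.0731 in each. The count was 0 with 1 value per series and 0 without the series block (smallest adjusted p for the named genes with 1 value per series, 0.447), 4 with array weights, 122 with series as a random block and 265 without the filter. Of the calls, 42.2% were up, against 31.1% with quantile normalization and 14.3% without rescaling.

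The lines did not share 1 course. Epcam, an epithelial adhesion gene, went from 11.74 at transplant 1 to 5.31, the floor, at transplant 5 in series 34, and from 11.62 to 5.58 in series 32, while in series 33 it was 11.24 and 11.59. The luminal list mean was 9.14 in series 34 at transplant 2 and 6.31, 6.28 and 6.24 at transplants 3, 4 and 5. In series 32 it went from 9.15 at transplant 2 to 7.60, 6.95 and 6.60, and in series 36 it reached 7.86 at transplant 5. Series 42 lay between 6.08 and 6.23 in every generation, and the other 7 series between 8.38 and 9.95. The basal myoepithelium mean went with it, from 9.36 to 7.21 in series 34 and from 9.13 to 7.37 in series 32 between transplants 2 and 3, while the mesenchymal mean went from 8.40 to 9.88 and from 8.78 to 10.21. Slopes differed among series for 2067 of 8499 genes (24.3%) by limma, led by Epcam (adjusted p = 3.41e-07), Bex3, Sdc4, Fxyd3 and Tnfrsf21. The count was 845 without series 25L, 453 with array weights and 997 with series 25L and 25R joined.

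**Figure D4:**
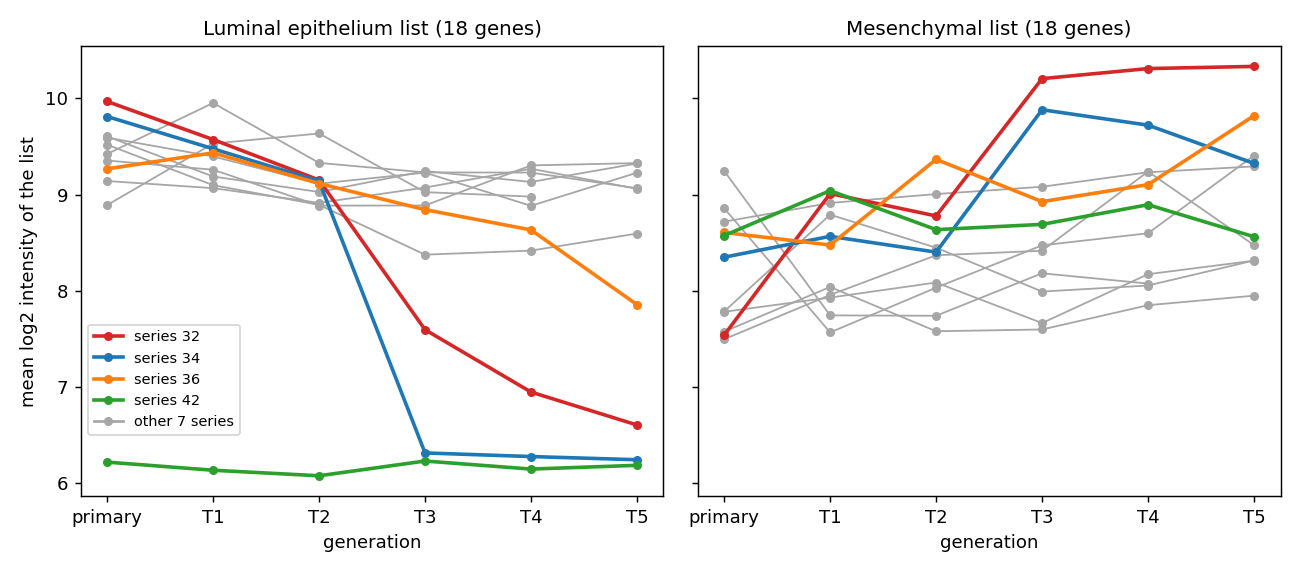
Mean log2 intensity (vertical axis) of the 18 luminal epithelium genes (left) and the 18 mesenchymal genes (right) in each tumor by generation (horizontal axis), with 1 line per series. Series 32, 34 and 36 leave the range of the other 7 series in the luminal list, and series 42 stays near 6 throughout.

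Of the genes set in advance, Krt8 and Krt14 were not called for the transplants, transplant 5 or the slope (Krt14 differed by 0.12 and -0.20 for the first 2). Esr1, Mmp9 and Pgr fell under the filter and were not tested, at the floor on 48, 45 and 18 of 65 arrays. The mean of Pgr over all arrays, 6.32, lay just under the cut of 6.35, and it averaged 7.01 in primary tumors and 6.18 in transplants. Esr1 averaged 5.89 and 5.35, and Mmp9 5.73 and 5.71. Hras had no probe set named here.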

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

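The tests of series 34, of cell shares and of the dim array of series 32 were chosen only after the results were seen. The tests that compare other splits of the samples and the test of RNA quality were planned.

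The transplant 5 tumor of series 32 stood apart from the other 9 of its generation in 7 measures. Its median intensity was 96.1 (others 143 to 172), 14.5% of its probe sets were at the floor (others 8.53 to 10.9), 433 probe sets read 1 (others 75 to 158), and its 10 brightest probe sets held 2.16% of the signal (others 1.43 to 1.76). Its list means were 10.12 for macrophages (others 8.80 to 9.43), 6.97 for mitosis (others 8.16 to 9.18) and 13.07 for ribosomal proteins (others 12.14 to 12.48). In series 13 the transplant 5 tumor had the highest adipocyte mean of its generation, 8.43 (others 6.77 to 7.38). In series 42 it had the lowest granulocyte mean, 6.36 (others 7.33 to 8.30). These 9 came from 39 measures of transplant 5, and chance gives such a gap in about 1 in 20 groups. The 7 of the series 32 array are not independent of each other, so that rate does not apply to their number. The other generations, with 11 arrays each, were not screened, since the test covered groups of at most 10 arrays.

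The fall of luminal epithelial genes over the transplants was uneven among series. Slopes differed among series for 2067 genes, and for 8 lists by permutation (100000 resamples, adjusted p). The adjusted p was 0.00033 for the luminal and the junction list (the smallest raw p, 1e-05, is the smallest they can give), 0.0014 for basal myoepithelium, 0.0033 for a list unnamed here, 0.0317 for mesenchymal genes and for the Wnt pathway, and 0.0363 for fibroblast matrix and for matrix proteases.

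In series 34 the luminal mean went from 9.14 to 6.31 between transplants 2 and 3, near the level of series 42. The highest correlation of the transplant 3, 4 and 5 arrays of series 34 with a series 42 array was 0.595, below the lowest correlation of 0.780 within series 42, which argues against these arrays holding series 42 tumors. The lowest correlation among the 3 arrays themselves was 0.55, and their highest with earlier arrays of series 34 was 0.03. Transplants 2 and 3 of series 34 correlated at -0.08, and a tumor from outside the 11 series or a wrong label at transplant 3 stays open. Array measures moved at the same step. In the primary tumor and transplants 1 and 2, 74, 82 and 78 probe sets read 1, against 138, 185 and 131 at transplants 3 to 5. The log2 3' to 5' actin ratio was 0.33, 0.26 and 0.51, against 0.09, 0.15 and 0.12. The Gapdh ratio was 0.17, 0.26 and 0.21, against 0.19, 0.15 and 0.16. Whether this shift bears on the luminal fall was not tested. A lower share of epithelial cells among other cells cannot be told apart from a change within tumor cells. The slopes of the fibroblast, endothelium, macrophage and T or NK cell lists did not differ beyond their spread (smallest adjusted exact sign-flip p = 0.313), which does not show that they were equal.

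The dim array of series 32 was also tested as a source of the luminal fall. Without it 3 luminal genes kept a called slope in place of 9, although the mean slope of the list was still -0.20 and 13 genes were called when adjusted over the list alone, so its part in the fall stays open. It does not account for the differences in slope, since 1525 of the 2067 genes stayed past the threshold without it. Loss of epithelial character with passage, a biological explanation the design allows, was not tested against these.

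The 807 genes that differed between transplants and primary tumors were weighed against RNA quality. With the 3' to 5' ratio of Gapdh as a covariate 401 of them remained called, just under 1 in 2, so RNA quality may account for part of the count. All 807 kept their direction, and the median absolute difference went from 0.32 to 0.30 and its median SE from 0.0883 to 0.0923. How far the lost calls lay from the threshold was not examined. The ratio was higher in the transplants in 8 of 11 series, by 0.06 ± 0.12 (SD) on average (exact sign-flip permutation p = 0.105). The actin ratio, not used as a covariate, averaged 0.33 in primary tumors and 0.32, 0.37, 0.25, 0.28 and 0.27 at transplants 1 to 5. The effect of transplantation itself stays among the open explanations.

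Chance can be excluded for the 807 genes (1 of 100 splits gave as many, the real one included, highest other 4), the 407 genes among generations (1 of 100, highest other 6), the 7099 among series (1 of 100, highest other 2) and the 2067 with different slopes (1 of 100, highest other 775). Splits that permute generations within a series, as for the 807, 407 and 2067 genes, remove the likeness of consecutive tumors (mean correlation 0.29 to 0.72). They exclude only a chance order of unrelated tumors, and drift along a line stays open. The permutations for the list slopes, of residuals over all transplant arrays, have the same limit. The splits for the 7099 genes cannot tell a difference between lines from a difference in how the arrays of a line were processed. For transplant 5 chance can be excluded by count (2 of 100), but the highest other split gave 1241 genes against the real 1197. It cannot be excluded for the 410 genes with a slope, as 6 of 100 splits gave as many and the highest other gave 1600. A split that gives several times the real count points to a structure of the samples, and which series it reversed was not examined. For transplant 1 the real count was 0, so that all 100 splits gave as many by construction (highest other 7), and the splits decide nothing there.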

How the results depend on the processing

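The fit with 1 value per series, the one without the transplant 5 array of series 32, the one with arrays not rescaled, the sign-flip tests with series 25L and 25R averaged and the joined count of slopes that differ were chosen only after the data were seen.

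The counts of genes that moved by more than 1.5 times are given with their setting, and the cause was not tested except where fewer arrays entered. Without a replicate block they were 8 among generations (407 with it), 85 for the transplants (807), 37 for transplant 5 (1197) and 0 for the slope (410; limma). With the block as a random effect the slope count was 122. With series 25L and 25R joined in 1 block, 997 genes differed in slope (2067). With 1 value per series the counts were 135 for the transplants, 133 for transplant 5 and 0 for the slope, and of these 133 and 130 were among the genes called with all arrays. Without the dim array of series 32 the slope count was 72.

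With array weights the counts were 331 for the transplants, 307 for transplant 5, 4 for the slope and 453 for slopes that differ. The lowest weights fell on transplant 5 of series 32 (0.12) and transplants 1 and 2 of series 25L (0.18 and 0.28). Transplants 3, 4 and 5 of series 34 were also among them (0.31, 0.25 and 0.27). With the Gapdh covariate 407 genes were called for the transplants. Without the filter 1 gene was called for transplant 1 and 265 for the slope. The cause was not tested.

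Leaving out 1 series at a time gave 195 to 569 genes among generations, 488 to 824 for the transplants, 764 to 1269 for transplant 5, 0 to 1 for transplant 1, 3 to 812 for the slope and 845 to 2300 for slopes that differ. The slope count was 3, 4 and 7 without series 36, 34 and 32, and 1 gene was called for transplant 1 without each of series 19, 32 and 34.

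No value that turned sign was past a threshold with the opposite sign. Of 84 list values that turned, 77 belonged to lists without a call. The other 7 belonged to ribosomal proteins, which were called upward at transplant 5 (0.098) and for the slope (0.014). The adjusted p of these calls was 0.700 and 0.839 with an estimated correlation, and 0.791 and 0.395 without the transplant 5 array of series 32. With array weights the log2 values that turned sign were 0.19 for Krt14 at transplant 5, 0.011 for red blood cells and -0.0049 for skeletal muscle over the transplants, and 0.014 for mast cells at transplant 5. The slopes were -0.00081 for endoplasmic reticulum stress, 0.012 for granulocytes, -0.00021 for hypoxia and glycolysis, -0.0034 for the proteasome, -0.0026 for red blood cells and -0.0049 for ribosomal proteins. Without the transplant 5 array of series 32, transplant 5 gave 0.040 for Krt14, -0.015 for interferon response and 0.031 for lipogenesis, and the slope gave -0.0014 for antigen presentation, -0.012 for red blood cells and -0.0034 for ribosomal proteins.

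With quantile normalization ribosomal proteins were at -0.016 for the transplants, -0.0072 at transplant 5 and -0.0090 for the slope. Transplant 5 gave -0.00024 for interferon response, -0.014 for matrix proteases and -0.029 for oxidative phosphorylation, and the slope gave -0.0022 for the proteasome and -0.0050 for red blood cells. With arrays not rescaled ribosomal proteins were at -0.0037, -0.017 and -0.0084, transplant 5 gave -0.083 for interferon response, -0.055 for matrix proteases, -0.058 for oxidative phosphorylation and -0.022 for the Wnt pathway, and the slope gave -0.011 for antigen presentation, -0.0076 for endoplasmic reticulum stress, -0.0087 for the proteasome and -0.015 for red blood cells. With a filter at the median, which tests fewer genes, the Wnt pathway was at -0.092, -0.28 and -0.054, immediate early genes at -0.0086 for the transplants, and mast cells at 0.0020 for transplant 5 and 0.0031 for the slope. With all probe sets the slope was -0.022 for antigen presentation and 0.0036 for immediate early genes. With the Gapdh covariate interferon response was at -0.0013 for transplant 5. The cause was not tested.

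Among values that turned sign when 1 series was left out, those for the transplants ranged from -0.064 to 0.34 for Krt14, -0.0985 to 0.0473 for basement membrane, -0.13 to 0.0054 for mast cells, -0.087 to 0.019 for red blood cells, -0.0078 to 0.12 for skeletal muscle, -0.0020 to 0.17 for interferon response, -0.12 to 0.021 for matrix proteases and -0.31 to 0.0090 for basal myoepithelium. At transplant 5 they ranged from -0.46 to 0.18 for Krt14, -0.12 to 0.037 for mast cells, -0.13 to 0.081 for red blood cells, -0.080 to 0.040 for lipogenesis, -0.22 to 0.019 for skeletal muscle, -0.11 to 0.14 for interferon response and -0.014 to 0.099 for matrix proteases. Slopes ranged from -0.038 to 0.0035 for basement membrane, -0.032 to 0.0027 for mast cells, -0.032 to 0.0011 for immediate early genes, -0.022 to 0.028 for red blood cells, -0.063 to 0.0013 for skeletal muscle, -0.0049 to 0.025 for antigen presentation, -0.0057 to 0.020 for ribosomal proteins, -0.034 to 0.0097 for granulocytes and -0.018 to 0.0014 for oxidative phosphorylation. The cause was not tested.

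Of 203 called values of named genes, 36 stayed past the threshold with 1 value per series, 57 with array weights, 149 with the Gapdh covariate and 188 with quantile normalization, and 13 without the block. The sign-flip calls of DNA replication and antigen presentation were lost with series 25L and 25R averaged to 1 value (adjusted p = 0.0938 each), where fewer values limit what the test can call. Signal near the floor limits what dim genes can show.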

Other observations

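No hypothesis was tested on the following values, which were chosen only after they were seen.

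Skeletal muscle genes were bright in a few tumors. The muscle list had a median of 6.95 over the 65 arrays, and 6 arrays lay more than 1 above it: transplant 3 of series 25L (9.77) and 25R (8.88), transplant 2 of series 33 (8.56) and 25L (8.29), the primary tumor of series 42 (8.28) and transplant 5 of series 34 (8.13). In transplant 3 of series 25L the skeletal actin gene Acta1 was at 12.36 (median of all arrays 5.31), the muscle creatine kinase gene Ckm at 11.62 (6.38), the calcium pump gene Atp2a1 at 11.16 (6.53) and the troponin gene Tnnt3 at 10.12 (6.77).

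Series 42 had low luminal, basal and junction means in all 6 generations, at 6.08 to 6.23, 6.64 to 6.85 and 6.87 to 7.18. Its milk secretion mean was 8.02 in the primary tumor and 6.99 at transplant 5, and its mitosis mean was 8.67 to 9.26. In series 10 the fibroblast matrix mean went from 10.71 in the primary tumor to 7.38 at transplant 1, and in series 32 from 7.22 to 9.93.

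Correlation between consecutive generations of 1 series, after the mean of each generation was removed, averaged 0.29 for primary and transplant 1, 0.47 for transplants 1 and 2, 0.48 for transplants 2 and 3, 0.72 for transplants 3 and 4 and 0.55 for transplants 4 and 5.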
